A study of Homo sapiens with 24 samples.

How the data were processed

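Total RNA of 24 HepG2 libraries was analysed, 3 biological replicates for each of 4 clonal lines with and without Dox. Per the labels, libraries were strand-specific and made from ribosome-depleted RNA, and ERCC spike-in RNAs had been added to the extracted RNA. Per the submitters' processing notes, reads were aligned with HISAT2 to hg19 and counted with HTSeq. The versions of these tools, the gene lengths and the treatment of reads with several matches were not given in the sources used here. The deposited values are TPM for 27672 RefSeq gene symbols and 92 ERCC spike-ins, whose TPM are part of each library's total. Read totals are not given, so depth is unknown. A relative depth was taken from the spacing of the TPM below 0.5, and ranged from 0.918 to 1.15. Of the symbols 25467 matched the RefSeq table at hand, or 26727 with synonyms. That table is on a later genome build, so no coordinates are given.

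The spike-ins were left out. Each library was divided by a median-of-ratios factor taken over 10832 genes at a TPM of 1 or more in all 24 libraries (factors from 0.8648 to 1.057). Genes at a TPM of 1 or more in at least 3 libraries were tested, 12690 in all, as log2(scaled TPM + 1). A pseudocount of 1 makes fold changes of low genes smaller than the ratio of their TPM. The model had a mean for each of the 8 groups and 16 residual degrees of freedom. It was fitted with limma 3.58.1 in R 4.3.3 with the trend and robust settings, and p-values were adjusted by the Benjamini-Hochberg method over the genes tested and called under 0.05. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

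The comparisons, the 38 gene lists and the rule for named genes were fixed before the data were examined. Comparisons were Dox against no Dox in each line, the mean of both control lines, the mean knockdown effect (mean Dox change of the TRIM33 lines minus that of the control lines), the same for each shRNA, genes called with both shRNAs in the same direction, the difference between the shRNAs, and TRIM33 lines against control lines with and without Dox. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 37 lists with at least 3 tested members. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance in 1 direction, were run beside it. The list of mitochondrial-genome mRNAs had too few tested members and was not analysed here. For the mean knockdown 17 lists were called, of which 6 held with an estimated correlation: S phase, endoplasmic reticulum chaperones, purine and pyrimidine synthesis, beta-oxidation and interferon-stimulated genes.

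Named genes were TRIM33; the 10 largest and 10 smallest mean knockdown changes among genes called with both shRNAs in the same direction, small noncoding RNAs left out; the 4 members with the smallest p of each called list and of the coenzyme Q, pyrimidine and ATF4 lists; the 5 largest changes each way among genes called alike in both control lines; and the 3 largest each way for the difference between the TRIM33 lines and for the uninduced lines. A list member that met this rule was left out of the text.

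On simulated data with 12331 genes, 37 of 49 genes with a true change of 1.25-fold were recovered for the mean knockdown. At 1.5-fold 49 of 50 were recovered, at 2-fold 48 of 49 and at 4-fold 48 of 48. There were 7 false calls (3.7% of calls). In the simulation few genes changed, the noise was independent and no line had its own Dox response. Its share of false calls therefore does not carry over to these data, where most genes were called. Alternatives tried were other scalings (deposited TPM, quantile normalization, small noncoding RNAs removed), a pseudocount of 0.1, other filters on low values, limma without trend and robust settings, library weights, each line fitted alone, each control line alone, a replicate block, a minimum log2 change of 1, and leaving out each of the 24 libraries. Whether spike-ins were added per mass of RNA or per cell was not given in the sources used here. The 39 spike-ins at a TPM of 10 or more in all libraries kept their ratios to each other, with an SD of 0.048 to 0.124 (log2) in a library around their means, so no difference in mix was seen. Scaling by the spike-ins, and leaving out replicate 1 of both uninduced control groups, were added after the data were seen. Correlations were taken across genes, which are not independent replicates.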

Results

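RNA was measured in clonal lines of HepG2, a human hepatocellular carcinoma line, that carry a doxycycline-inducible short hairpin RNA (shRNA). There were 4 lines, 2 with non-targeting shRNAs (control shRNA-1 and control shRNA-2) and 2 with shRNAs against TRIM33 (shRNA-548 and shRNA-942). TRIM33, also called TIF1γ, is a chromatin-associated regulator of transcription. Each line received doxycycline (Dox) at 1 µg/ml or its solvent for 48 h in 3 biological replicates, which gave 8 groups of 3 and 24 libraries of ribosome-depleted, strand-specific RNA. The design asks how gene expression changes when TRIM33 is lowered. The deposited TPM keep no read totals, so the depth is unknown. The spacing of the lowest values put the libraries at 0.918 to 1.15 times a common depth, and each library had between 11628 and 12120 genes at a TPM of 1 or more. After filtering, 12690 genes were tested with limma. Each shRNA is represented by 1 clonal line, so an effect of an shRNA and an effect of its clone cannot be separated, and the p-values measure the spread between replicates of a clone.

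TRIM33 mRNA fell upon Dox in both TRIM33 lines and in neither control line. In the shRNA-548 line it went from 29.9 ± 0.574 to 18.2 ± 0.653 scaled TPM (SD, n = 3), a log2 change of −0.69. In the shRNA-942 line it went from 26.4 ± 0.94 to 9.77 ± 0.407 scaled TPM (SD, n = 3), a log2 change of −1.35. These are changes of −37.9% and −60.7% on the log2(value + 1) scale, with adjusted p of 1.79e-12 and 5.66e-18 (limma, Benjamini-Hochberg). The fall was larger with shRNA-942, by 0.66 on the log2 scale (adjusted p = 4.13e-09, limma). TRIM33 was at 31 ± 2.22 and 31.4 ± 0.547 scaled TPM without and with Dox in the control shRNA-1 line (SD, n = 3; log2 difference 0.02). It was at 28.7 ± 1.13 and 30.5 ± 0.617 in the control shRNA-2 line (SD, n = 3; log2 difference 0.09). Neither control difference passed the test (adjusted p = 0.853 and 0.113, limma), and the sign in the control shRNA-1 line depended on replicate 1 of its uninduced group, without which the difference was −0.04.

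**Figure D1:**
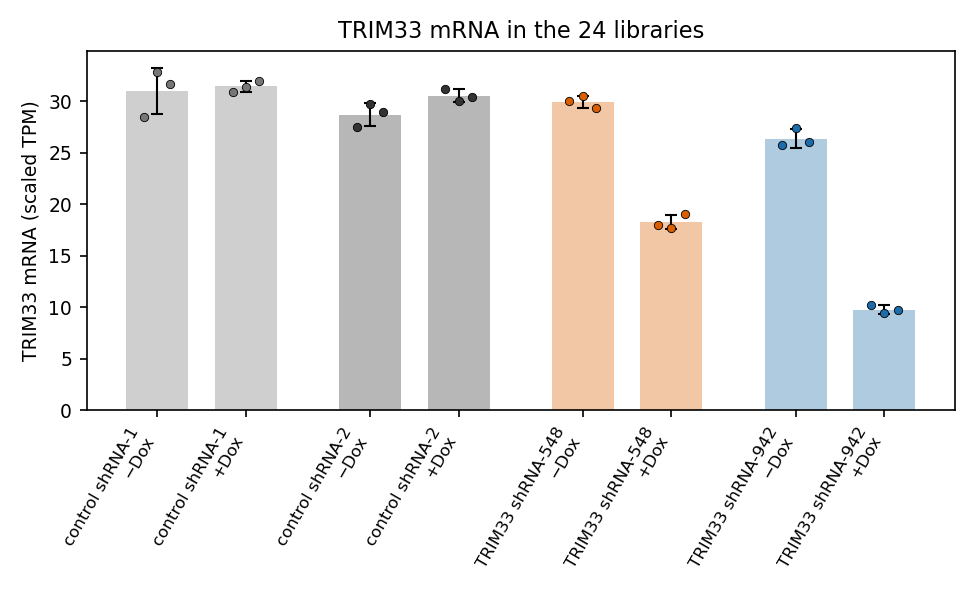
TRIM33 mRNA in scaled TPM (y axis) in the 8 groups (x axis); points are libraries, bars are group means and error bars are SDs (n = 3). Induced libraries average 18.2 with shRNA-548 and 9.77 with shRNA-942, against 30.5 or more in the induced control lines.

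Dox alone, or induction of a non-targeting shRNA, was examined in the control lines. The responses of the control lines were unlike each other. In the control shRNA-1 line 729 genes passed the test, 391 higher and 338 lower, and 1 of them changed 2-fold or more. Fitted on its own 6 libraries this line gave 51 genes, with library weights 2346 and with the deposited TPM 386. In the control shRNA-2 line 6129 passed, 3073 higher and 3056 lower, with 158 changed 2-fold or more. The difference between the control lines was itself called for 4723 genes (limma). Of 526 genes called in both lines, 312 moved in opposite directions, and across genes the changes had r = −0.09. Genes are not independent replicates, so these correlations only describe the libraries. The count for control shRNA-1 went down to 310 without its induced replicate 3 and to 319 without its induced replicate 2. With scaling by the spike-in RNAs, chosen after the data were seen, 8 genes were called in control shRNA-1, and 1608 in control shRNA-2, 1277 higher and 331 lower.

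Few genes moved alike in both control lines. GLUD1, which encodes mitochondrial glutamate dehydrogenase, rose by 0.63 in control shRNA-1 and 1.34 in control shRNA-2 (log2; mean 0.99, adjusted p = 5.21e-15, limma). GLUD2, a near-identical copy whose reads may not be separable from those of GLUD1, rose by a mean of 0.92. SDC4, a cell-surface proteoglycan, SLC5A11 and DGCR8, a microRNA-processing factor, rose by a mean of 0.67, 0.62 and 0.62. SLC6A14, an amino acid transporter, NR6A1, CCDC68, MGC12916 and ENC1 fell, with log2 means of −1.01, −0.88, −0.82, −0.66 and −0.65. Over the mean of both control lines 4564 genes were called, 2279 higher and 2285 lower, and 5 changed 2-fold or more. With spike-in scaling 441 were called, 285 higher and 156 lower.

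Gene lists fixed before the data were examined moved in the controls too, mostly through control shRNA-2. Of the fatty acid beta-oxidation genes 17 of 19 rose in the control mean and none fell (median log2 0.15, adjusted p = 1.45e-08, limma's camera). Of 22 cholesterol synthesis genes 18 rose and none fell (median 0.13, adjusted p = 6.61e-07, camera). Interferon-stimulated genes had 13 of 26 higher and 1 lower (adjusted p = 0.000123, camera). On the lower side were 15 of 19 endoplasmic reticulum chaperones (median −0.12, adjusted p = 2.47e-06, camera) and 36 of 51 replication-dependent histones (adjusted p = 1.18e-07, camera). Adjusted over the list alone, 19 cholesterol genes rose and 1 fell, 14 interferon-stimulated genes rose and 38 histones fell. With an estimated correlation the adjusted p was 0.00263 for beta-oxidation, 0.0115 for cholesterol synthesis, 0.00833 for interferon-stimulated genes, 0.00833 for the chaperones and 0.489 for the histones. The knockdown effect was taken as the Dox change in the TRIM33 lines minus the mean Dox change in the control lines.

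With the mean knockdown contrast most expressed genes were called. S phase, nucleotide synthesis and endoplasmic reticulum chaperone genes were lower, and fatty acid beta-oxidation and interferon-stimulated genes were higher. For this mean these calls held with camera at a preset and at an estimated correlation, but not all of them held with each shRNA alone. Of 12690 genes 9675 were called (76.2%), 5206 higher and 4469 lower, and 508 rose and 511 fell 2-fold or more. Many called changes were small, the median standard error being 0.058 on the log2 scale. Pairings of the 4 lines that do not follow the shRNA target called 7636 and 7199 genes, but 211 and 166 at 2-fold or more. All changes are relative to the median gene. With scaling by the spike-ins the median gene itself lay 0.52 lower (log2 −0.52), and of 8698 calls 795 were higher and 7903 lower. Whether the spike-ins were added per mass of RNA or per cell is not given in the sources used here, so these values cannot be read as amounts per cell. The share of TPM taken by the spike-ins went from 10.6 ± 1.5% to 17.4 ± 3.1% upon Dox with shRNA-942 and from 7.83 ± 0.772% to 10.3 ± 0.82% with shRNA-548 (SD, n = 3).

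The largest rises with both shRNAs were in GSTA1 and GSTA2, which encode alpha-class glutathione transferases, by 4.45 ± 0.05 and 4.42 ± 0.08 (log2 ± SE), or 21.8-fold and 21.4-fold. The reads of this near-identical pair may not be separable. GSTA1 went from 17.7 ± 0.65 to 535 ± 12 scaled TPM with shRNA-548 and from 29.4 ± 0.62 to 1740 ± 32 with shRNA-942 (SD, n = 3), but it also rose in control shRNA-2, from 22.5 ± 0.56 to 83.3 ± 4.3. PGLYRP2, a liver-secreted amidase of peptidoglycan, rose 15.4-fold. CYP7A1, the rate-limiting enzyme of bile acid synthesis, rose 6.73-fold (log2 2.75 ± 0.11, adjusted p = 2.87e-16, limma). WFDC21P, PLEK2, PRR15L, ERP27, RBP2, a cytoplasmic retinol-binding protein, and MYO1A completed the 10 largest rises, between 6.88-fold and 12.5-fold.

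The largest fall was in IGFBP1, a secreted binding protein of insulin-like growth factors, by 5.00 ± 0.18 on the log2 scale, or 32.1-fold (adjusted p = 8.9e-15, limma). It went from 258 ± 43 to 1.54 ± 0.44 scaled TPM with shRNA-548 and from 332 ± 28 to 4.8 ± 0.19 with shRNA-942 (SD, n = 3). The transcription factors ETV4 and ETV5 fell 18.1-fold and 8.82-fold, and CCL20, a chemokine, fell 9.26-fold. HK2, a hexokinase, and SLC2A1, the glucose transporter GLUT1, fell 9.03-fold and 5.89-fold. ANKRD1, NES, IER3 and DUSP6, a phosphatase that acts on ERK, fell between 5.87-fold and 6.87-fold. All 20 genes met the rule of moving alike with both shRNAs. Of the 10 that fell, IGFBP1, ETV4, CCL20, HK2, ETV5, IER3, SLC2A1 and DUSP6 also fell with Dox in control shRNA-2, with log2 changes between −0.96 and −2.36, whereas ANKRD1 rose there by 0.46. Of the 10 that rose, GSTA1, GSTA2, PGLYRP2, PRR15L, ERP27, RBP2 and CYP7A1 also rose there, by between 0.94 and 1.93.

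**Figure D2:**
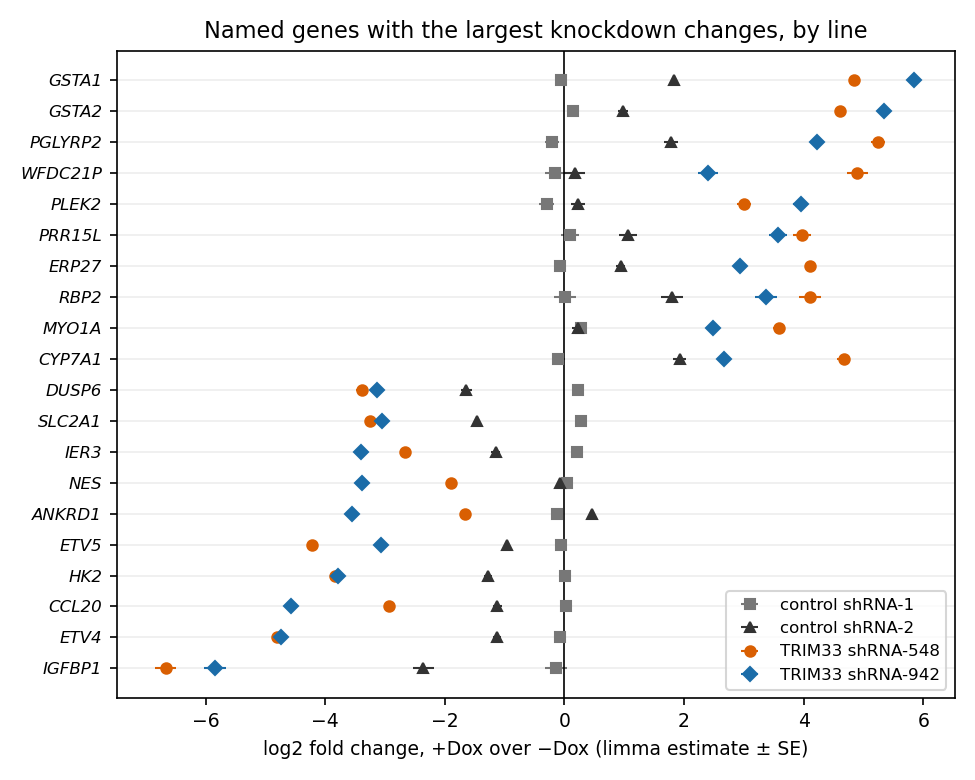
Log2 change upon Dox (x axis, limma estimate; error bars are standard errors, 3 against 3 libraries) of the 10 named genes with the largest rises and the 10 with the largest falls (y axis), with a symbol per line. IGFBP1 reaches −6.67 with shRNA-548 and −5.84 with shRNA-942, against −2.36 in control shRNA-2 and −0.14 in control shRNA-1.

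Cell cycle genes fell. Of 32 S phase genes 32 fell and none rose, with a median of −1.12 (adjusted p = 1.94e-16, camera). CDC6, which loads the replicative helicase, fell by 2.00 ± 0.03 on the log2 scale, CDC45 by 1.85 ± 0.04, UHRF1 by 1.65 ± 0.03 and MCM3 by 1.21 ± 0.02 (each ± SE). Of 34 G2 and M phase genes 33 fell and 1 was not called (median −0.88, adjusted p = 6.82e-14, camera). Among them ANLN, CCNB1, BUB1 and AURKA fell by 1.22, 1.16, 1.04 and 0.88. Of 51 replication-dependent histones 44 fell and none rose (median −0.95, adjusted p = 6.92e-13, camera), with HIST1H2AB at −1.62 and HIST1H4D at −1.46. Histone copies resemble each other, so single members are uncertain. Adjusted p with an estimated correlation was 0.00156 for S phase, 0.0645 for G2 and M phase and 0.200 for histones.

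Nucleotide synthesis genes fell with them. Of 13 genes of de novo purine synthesis 12 fell and none rose (median −0.59, adjusted p = 1.66e-05, camera), including PAICS, GART, ADSL and PFAS by 1.15, 1.02, 0.90 and 0.76 on the log2 scale. All 11 genes of de novo pyrimidine and thymidylate synthesis fell (median −0.34, adjusted p = 0.000156, camera), including RRM2, DTYMK and RRM1 by 1.26, 1.16 and 0.70. Both calls held with an estimated correlation (adjusted p = 0.00172 and 0.0140).

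Glycolysis genes were lower and genes of lipid use and hepatocyte function were higher. Of 19 glycolysis genes 15 fell and 1 rose (median −0.62, adjusted p = 1.58e-05, camera; adjusted p = 0.206 with an estimated correlation). Besides HK2 and SLC2A1, LDHA fell by 1.57 ± 0.04 and ENO1 by 1.11 ± 0.04 (log2 ± SE). Of 21 targets of hypoxia-inducible factor 11 fell and 4 rose (median −0.17, adjusted p = 0.0476, camera; adjusted p = 0.628 with an estimated correlation), with SLC2A3, LOX and PDK1 at −1.43, −1.44 and −1.15. This call was also lost with control shRNA-2 alone (adjusted p = 0.116), a higher filter (adjusted p = 0.108), quantile normalization (adjusted p = 0.0618), library weights (adjusted p = 0.0571) and a replicate block (adjusted p = 0.0528), and without any 1 of 11 libraries (adjusted p between 0.0503 and 0.0792). These were replicate 3 of the induced and replicate 1 of the uninduced control shRNA-1 groups, replicate 3 of both control shRNA-2 groups, replicates 2 and 3 of the induced and 1 of the uninduced shRNA-548 groups, and the 3 induced libraries and replicate 3 of the uninduced ones with shRNA-942. Of 19 fatty acid beta-oxidation genes 17 rose and 2 fell (median 0.54, adjusted p = 9.87e-05, camera), and this held with an estimated correlation (adjusted p = 0.0140). With spike-in scaling their median was −0.09, which lay 0.43 above the median gene. SLC25A20, the mitochondrial carnitine carrier, rose by 1.17 ± 0.05, ACAA2 by 0.75 ± 0.03, and HADHB and HADHA, the subunits of the trifunctional protein, by 0.74 ± 0.02 and 0.60 ± 0.02. With spike-in scaling HADHB (0.08), ACAA2 (0.09) and HADHA were not called (adjusted p = 0.694 and 0.664 for the former pair), and HADHA had the opposite sign (log2 −0.06).

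Of 23 hepatocyte transcription factors and enzymes 18 rose and 1 fell (median 0.61, adjusted p = 0.000855, camera; adjusted p = 0.0643 with an estimated correlation). The member that fell was NR0B2, the repressor SHP, by 1.64, while CYP7A1 rose, as did PCK1, of gluconeogenesis, by 1.64 and CYP27A1 by 0.87. Of 25 hepatocyte secreted proteins 17 rose and 6 fell, or 18 rose when adjusted over the list alone (median 0.52, adjusted p = 0.00373, camera; adjusted p = 0.482 with an estimated correlation). This call was lost with control shRNA-2 as the only control (median 0.20, adjusted p = 0.0520). The list moved apart in the control lines, with 12 lower and 0 higher in control shRNA-1 and 16 higher and 4 lower in control shRNA-2 (adjusted p = 2.17e-08 and 2.26e-05, camera; adjusted p = 0.375 and 0.395 with an estimated correlation). SERPINC1, ITIH3 and FGG rose by 1.34, 1.80 and 0.82, and APOA2 fell by 1.95. Of 22 cholesterol synthesis genes 13 rose and 4 fell, or 14 rose when adjusted over the list alone (median 0.20, adjusted p = 0.0253, camera; adjusted p = 0.206 with an estimated correlation). The cholesterol call was also lost with control shRNA-2 as the only control (median 0.08, adjusted p = 0.204), with the deposited TPM (adjusted p = 0.0647) and with spike-in scaling (adjusted p = 0.488). TM7SF2, MSMO1, LSS and NSDHL rose by 1.31, 0.82, 0.73 and 0.50. With spike-in scaling LSS (0.07), MSMO1 (0.16), CYP27A1 (0.21) and FGG (0.15) were not called (adjusted p = 0.742, 0.411, 0.271 and 0.405), and NSDHL lost its call and changed sign (log2 −0.16). With spike-in scaling the medians of these 3 lists were −0.05, −0.14 and −0.44, which lay 0.47, 0.38 and 0.08 above the median gene.

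Interferon-stimulated genes rose and stress-response genes fell. Of 26 interferon-stimulated genes 21 rose and 4 fell (median 0.66, adjusted p = 0.000226, camera; adjusted p = 0.00776 with an estimated correlation), with IFI6, IFIT1, MX1 and IFIH1 at 1.45, 1.37, 1.36 and 1.14. All 19 endoplasmic reticulum chaperones and related genes fell (median −0.74, adjusted p = 5.64e-09, camera; adjusted p = 0.00172 with an estimated correlation). CANX, which encodes calnexin, fell by 1.27, PDIA4 by 0.86, HSPA5, which encodes BiP, by 0.85 and XBP1 by 0.82. The log2 Dox effect with shRNA-548 minus that with shRNA-942 was −2.51, −1.40, −0.95 and −0.80 for these 4 genes. The falls were thus larger with shRNA-548, and that of CANX came almost wholly through that line. Of 29 genes of ATF4 and the integrated stress response 18 fell and 7 rose (median −0.38, adjusted p = 0.0210, camera; adjusted p = 0.206 with an estimated correlation), with GDF15, STC2, SLC7A1 and MTHFD2 lower by 1.58, 1.07, 0.94 and 0.79. The call was also lost with quantile normalization (adjusted p = 0.0545) and a higher filter on mean TPM (adjusted p = 0.0577).

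**Figure D3:**
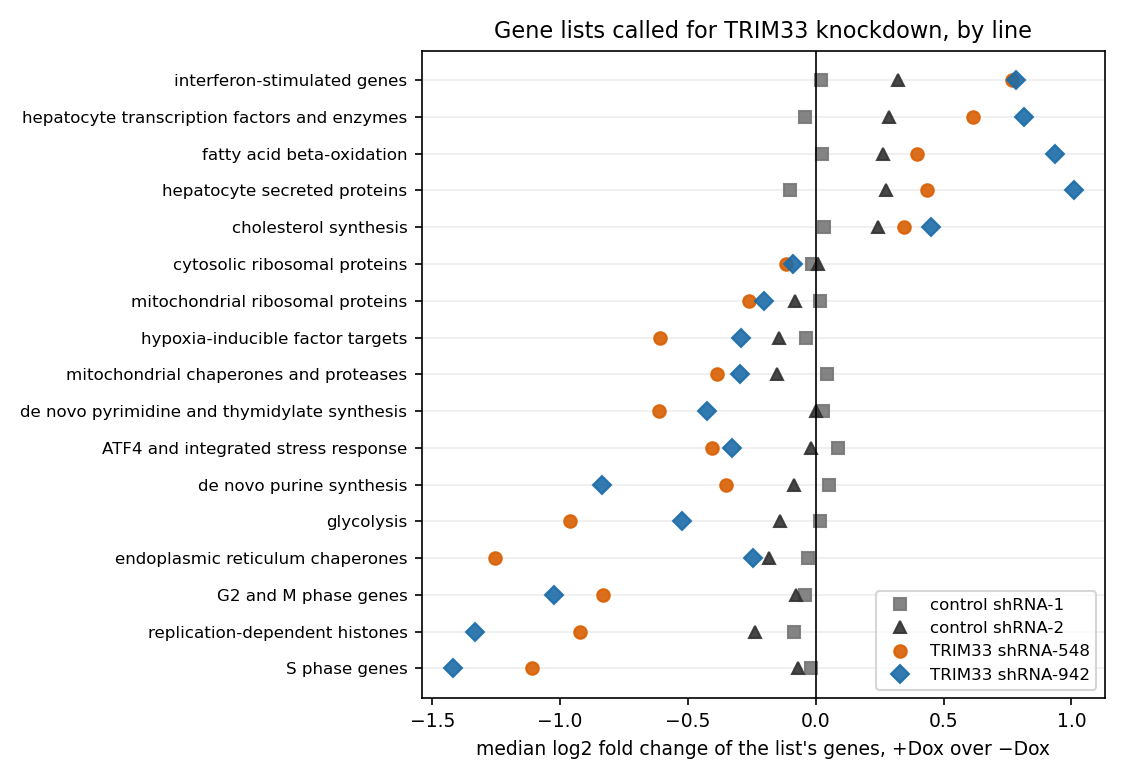
Median log2 change upon Dox (x axis) of the genes of each list called for the mean knockdown (y axis, 17 lists), with a symbol per line (3 against 3 libraries). S phase genes lie at −1.11 with shRNA-548 and −1.42 with shRNA-942, against −0.02 and −0.07 in the control lines. With spike-in scaling the knockdown medians of the beta-oxidation, cholesterol and both hepatocyte lists fell below 0.

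Mitochondrial genes did not move as a block. Of 13 genes of coenzyme Q synthesis 6 rose, 5 fell and 2 were not called, and the list as a whole was not called (median 0.06, mean −0.01, adjusted p = 0.913, camera). COQ10A rose by 1.04 ± 0.06, whereas the methyltransferase COQ3 fell by 1.08 ± 0.07, COQ7 by 0.60 ± 0.04 and PDSS1 by 0.48 ± 0.06 (log2 ± SE). COQ3 went from 16 ± 0.96 to 7.33 ± 0.47 scaled TPM with shRNA-548 and from 17.8 ± 0.72 to 8.08 ± 1.1 with shRNA-942 (SD, n = 3). Nuclear-encoded subunits of complex I had 18 of 37 higher and 12 lower, those of complexes II, III and IV had 4 of 24 higher and 14 lower, those of the ATP synthase had 4 of 16 higher and 6 lower, and tricarboxylic acid cycle genes had 8 of 21 higher and 9 lower. None of these 4 lists was called (adjusted p = 0.913, 0.105, 0.619 and 0.457, camera). The counts ran in opposite directions with each shRNA. Subunits of complexes II, III and IV had 2 of 24 higher and 20 lower with shRNA-548 (adjusted p = 0.000671, camera; adjusted p = 0.149 with an estimated correlation), but 13 higher and 2 lower with shRNA-942 (adjusted p = 0.160, camera). ATP synthase subunits had 1 of 16 higher and 10 lower with shRNA-548 (adjusted p = 0.0154, camera; adjusted p = 0.270 with an estimated correlation), but 11 higher and 2 lower with shRNA-942 (adjusted p = 0.101, camera). Complex I had 8 higher and 18 lower with shRNA-548 and 23 higher and 7 lower with shRNA-942, without a call for either.

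Of 74 mitochondrial ribosomal proteins 42 fell and 11 rose (median −0.14, adjusted p = 0.00099, camera; adjusted p = 0.122 with an estimated correlation), among them MRPL20, MRPS23, MRPS34 and MRPL3 by 1.27, 1.04, 0.97 and 0.66. Of 14 mitochondrial chaperones and proteases 10 fell and 3 rose (median −0.21, adjusted p = 0.0280, camera; adjusted p = 0.0693 with an estimated correlation), with TRAP1, HSPE1, HSPD1 and HSPA9 lower by 0.93, 0.81, 0.74 and 0.41. Of 75 cytosolic ribosomal proteins 44 fell and 3 rose, or 41 and 2 when adjusted over the list alone (median −0.10, adjusted p = 0.00373, camera; adjusted p = 0.628 with an estimated correlation). Their call was lost with quantile normalization (adjusted p = 0.574, camera) and without small noncoding RNAs (adjusted p = 0.0574). Quantile normalization also ended the calls of the mitochondrial ribosomal proteins (adjusted p = 0.0618) and the mitochondrial chaperones (adjusted p = 0.127), and the latter call was lost with control shRNA-2 alone (adjusted p = 0.0780) and a higher filter (adjusted p = 0.0814). RPL26 and RPS27A stood apart from this small shift at −1.17 and −1.12, each through a single line, and RPL9 and RPL6 fell by 0.42 and 0.36. For the other lists called, the counts adjusted over the list alone were the same as those over all genes.

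The remaining lists were not called for the mean knockdown with camera (adjusted p between 0.0927 and 0.659). The numbers higher and lower were 4 and 12 of 20 NRF2 targets, 14 and 6 of 24 p53 targets (15 and 6 adjusted over the list alone), 7 and 10 of 18 TGF-beta and BMP targets, and 6 and 8 of 14 TIF1 family and SMAD pathway genes. They were 15 and 5 of 25 transcription elongation factors (16 and 5 adjusted over the list alone), 4 and 6 of 10 serine and folate one-carbon genes, 4 and 7 of 11 fatty acid synthesis genes, 8 and 3 of 12 genes of haem synthesis and breakdown, and 4 and 2 of 7 bile acid and farnesoid X receptor targets. Acute-phase and NF-kappaB targets had 5 and 5 of 14 (5 and 6 adjusted over the list alone), and small noncoding RNAs had 46 and 15 of 165 (44 and 13 adjusted over the list alone). Of markers of other cell types, 4 of 23 erythroid genes were expressed highly enough to test, and 3 rose and 1 fell. Biliary and progenitor markers had 2 higher and 6 lower of 10, mesenchymal and stellate markers 4 and 3 of 8, and leukocyte and endothelial markers 4 and 2 of 7. Medians and means had opposite signs for coenzyme Q, ATP synthase, fatty acid synthesis, mesenchymal and leukocyte lists.

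Each TRIM33 shRNA was also set against the control mean on its own. With shRNA-548 9284 genes were called, 4928 higher and 4356 lower, and with shRNA-942 9220, 4967 higher and 4253 lower. With spike-in scaling the counts were 6027, 1057 of them higher, and 9136, 505 of them higher. The S phase median was −1.06 with shRNA-548 and −1.30 with shRNA-942, and the purine synthesis median was −0.39 and −0.87. The endoplasmic reticulum chaperone median was −1.19 with shRNA-548, where all 19 fell, and −0.20 with shRNA-942, where 11 fell and 2 rose. The hepatocyte secreted protein median was 0.28 with shRNA-548 (14 higher and 9 lower, adjusted p = 0.297, camera) and 0.94 with shRNA-942 (22 higher and 3 lower). Of the lists called for the mean, cholesterol synthesis was not called with shRNA-548 (adjusted p = 0.136), nor hypoxia and ATF4 targets with shRNA-942 (adjusted p = 0.16 and 0.15). Camera with an estimated correlation called 5 lists with shRNA-548 and 4 with shRNA-942. It did not call beta-oxidation with shRNA-548 (median 0.24, 12 higher and 3 lower, adjusted p = 0.149). Nor did it call pyrimidine synthesis with shRNA-942 (median −0.43, 1 higher and 9 lower, adjusted p = 0.0605). Endoplasmic reticulum chaperones, with their median of −0.20, were also not called with shRNA-942 at an estimated correlation. Some lists were called with a single shRNA. With shRNA-548 NRF2 targets had 13 of 20 lower and 2 higher (median −0.34, adjusted p = 0.00096, camera; adjusted p = 0.0990 with an estimated correlation), against a median of −0.02 with shRNA-942. TGF-beta and BMP targets had 11 of 18 lower and 4 higher with shRNA-548 (median −0.36, adjusted p = 0.0154, camera; adjusted p = 0.176 with an estimated correlation), against a median of −0.26. With shRNA-942 p53 targets had 16 of 24 higher and 7 lower (median 0.71, adjusted p = 0.0167, camera; adjusted p = 0.0559 with an estimated correlation), against 0.20 with shRNA-548. Acute-phase and NF-kappaB targets had 8 of 14 lower and 4 higher with shRNA-942 (median −0.43, adjusted p = 0.0418, camera; adjusted p = 0.236 with an estimated correlation), against 0.20. The difference between the shRNAs was not tested for lists. Of 7216 genes called with both shRNAs 3083 rose with both, 2677 fell with both and 1456 (20.2%) moved in opposite directions. With spike-in scaling 284 rose and 4428 fell with both. Independent lists would share 1929 rises and 1460 falls. Across genes the changes had r = 0.578 and a covariance of 0.245. Simulated unchanged lines that shared their controls in the same way gave 0.331 and 0.00361. The simulated controls had no Dox response either, whereas the real control response was subtracted for both shRNAs. The simulated covariance therefore leaves out what that shared response adds. With the controls split between the shRNAs r was 0.520 or 0.462, and 5123 or 5023 genes were called with both in the same direction. Changes of 2-fold or more with both shRNAs were found for 236 genes that rose and 248 that fell.

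**Figure D4:**
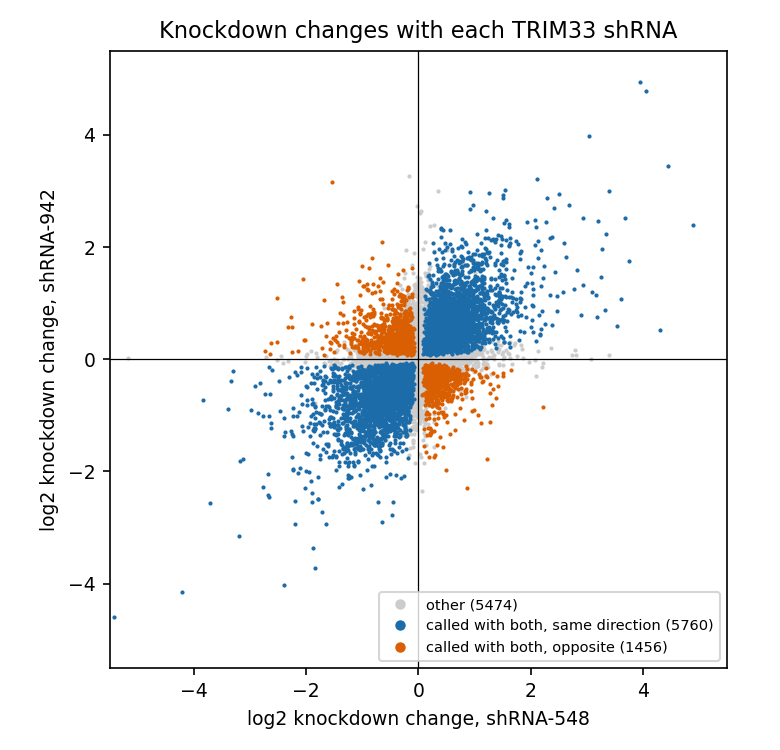
Log2 knockdown change of each tested gene with shRNA-548 (x axis) and shRNA-942 (y axis), both relative to the mean control change. 5760 genes were called with both in the same direction, 1456 with both in opposite directions, and 5474 were not called with both.

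The Dox effects of the TRIM33 lines differed for 8349 genes, 4119 higher and 4230 lower with shRNA-548, and 1089 of these differed 2-fold or more (limma). SPP1, which encodes osteopontin, fell from 390 ± 12 to 13.7 ± 1.3 scaled TPM with shRNA-548 and rose from 453 ± 4.3 to 624 ± 15 with shRNA-942 (SD, n = 3; difference of log2 changes −5.20, adjusted p = 1.07e-24, limma). BHMT, of betaine metabolism, went from 4.87 ± 0.68 to 1.51 ± 0.072 with shRNA-548 and from 2.06 ± 0.37 to 33.1 ± 1.8 with shRNA-942 (SD, n = 3; difference −4.70). HEPACAM changed by −2.54 with shRNA-548 and 1.07 with shRNA-942. CHGB, which encodes a secretory granule protein, rose by 4.34 with shRNA-548 and 0.54 with shRNA-942, and FSTL3 by 3.95 and 0.63. SOX4, a transcription factor, rose by 0.82 with shRNA-548 and fell by 2.35 with shRNA-942. With the deposited TPM unscaled, 5479 of 8377 such genes were higher with shRNA-548, and with spike-in scaling 4462 of 5180.

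The lines were also compared directly. With Dox, 10525 genes differed between the TRIM33 lines and the control lines, 5563 higher and 4962 lower, of which 1096 differed 2-fold or more. Without Dox 7021 genes already differed, 3457 higher and 3564 lower, of which 127 differed 2-fold or more. With spike-in scaling 1029 were higher and 9398 lower with Dox, and 584 higher and 1132 lower without. With the main scaling and without Dox, the histone genes HIST1H2AG, HIST1H2BJ and HIST1H2AH were higher in the TRIM33 lines by 4.38, 3.89 and 3.34 (log2). DPYS, RBM23 and ELK1 were lower there by 2.59, 2.44 and 2.09. DPYS, which encodes dihydropyrimidinase, was at 33.7 ± 0.72 scaled TPM in uninduced control shRNA-1, at 1.45 ± 0.44 in control shRNA-2 and at 1.37 ± 0.47 in shRNA-548 (SD, n = 3), and it was listed at 0 in the 3 uninduced shRNA-942 libraries. HIST1H2AG was at 80.8 ± 6.3 in control shRNA-1 and 2.41 ± 1.2 in control shRNA-2, so these differences run between single lines as well as between the shRNA targets. TRIM33 itself was 0.08 lower without Dox in the TRIM33 lines on the log2 scale (adjusted p = 0.0333, limma).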

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

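The tests of the control shRNA-2 response and of the difference between the TRIM33 lines, and the other pairings of the lines with Dox alone and without Dox, were chosen only after those results were seen.

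Control shRNA-2 responded to Dox unlike control shRNA-1, with 4723 genes differing between their responses (limma), and its response ran with that of the TRIM33 lines (r = 0.487 with shRNA-548 and 0.550 with shRNA-942 across genes). Slopes on its change were taken over the 158 genes it changed 2-fold or more, including IGFBP1, SLC2A1 and GSTA1. They were 1.218 with shRNA-548, 1.248 with shRNA-942 and −0.044 with control shRNA-1 (SE 0.012). This argues against a response to Dox itself shared by every line. Induction of the shRNA in the control shRNA-1 line was not tested here, so a response to any induced shRNA stays open. TRIM33 mRNA was 0.088 higher in log2 upon Dox, not lower, which argues against loss of TRIM33 mRNA. S phase genes had a median of −0.068 (95% bootstrap interval −0.128 to 0.017). For RNA from induced TRIM33 cells in these libraries a bound of −0.618 was set from the median fall in the TRIM33 lines. The interval lies above this bound, which argues against a large share of such RNA. A small share would move these genes little and was not excluded. A property of this clone or an effect of its shRNA sequence also stays open and was not tested.

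The Dox responses of the TRIM33 lines differed for 8349 genes (limma), and TRIM33 fell further with shRNA-942. A stronger version of the same changes, as the cause of all differences, is argued against by the 20.2% of genes called with both shRNAs that moved in opposite directions. Of the 497 genes changed 2-fold with both, however, only 13 moved in opposite directions. For these larger shared changes the directions do not count against a stronger version. Their slope was 1.01, against a ratio of 1.96 for TRIM33. Choosing genes changed 2-fold with both draws this slope toward 1, so it does not decide. The amount of RNA per spike-in is argued against as the whole cause because it moves every gene of a library alike: under the common shift that leaves the fewest, 1061 genes differed 2-fold or more, 538 higher and 523 lower, against 1089 without a shift. Small differences depend on the scaling, which was not settled. For the 437 genes changed 2-fold with 1 shRNA and by under 0.25 with the other, an off-target of an shRNA and a difference between clones cannot be told apart, because each shRNA has 1 clone.

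The mean knockdown changed 1019 genes 2-fold or more, whereas pairing the 4 lines in the other ways gave 211 and 166. The larger changes thus lay mostly between the TRIM33 lines and the control lines. The 4 lines allow only 3 pairings, so chance in their grouping could not be excluded. A response that the TRIM33 lines share for another reason would also cancel in the other pairings. These counts therefore do not decide the source of the larger changes. Smaller changes were common under every pairing, with 9675, 7636 and 7199 genes called, so a call alone says little about TRIM33. No biological explanation was tested for this pattern as a whole.

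Other splits of the samples were counted for each comparison. For Dox within a line the splits were too few for a share under 0.05. The real split stood at 729 genes against a highest other of 52 in control shRNA-1, at 6129 against 2 in control shRNA-2, and at 10013 against 0 with each TRIM33 shRNA, as the 1 split of 10 with so many genes. Elsewhere Dox labels were drawn at random within each line, so chance could be excluded only for the Dox labels of libraries within lines. This held for the mean of both control lines (4564 genes, highest other 697) and the mean knockdown (9675 and 5193). It also held for shRNA-548 (9284 and 8758), shRNA-942 (9220 and 8481) and genes called with both (5760 and 996). For the mean knockdown, chance in the grouping of the 4 lines could not be excluded, as other pairings called 7636 and 7199 genes. For TRIM33 against control lines, chance could be excluded only for the grouping of the 12 libraries, with Dox (10525 and 6789) and without (7021 and 4466). It could not be for the grouping of the 4 lines, of which other pairings gave 9056 and 9015 genes with Dox and 5283 and 6499 without. For the difference between the TRIM33 lines chance could be excluded for the Dox labels within lines too. Of 100 draws 2 reached 8349 genes, and the highest other had 10172. That draw, also the highest for each knockdown result, exchanged the Dox labels of all 6 shRNA-548 libraries and of none with shRNA-942, so it carries the real groups with a sign turned. The median of the other draws was 0.

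In the ERCC spike-ins, which were left out of the genes tested and served only as an alternative scaling, the share of TPM was 17.4 ± 3.1% in the induced shRNA-942 libraries (SD, n = 3), against 8.91 ± 0.919% and 8.11 ± 0.727% in the induced control lines. Upon Dox in that line 39 spike-ins rose by a mean log2 of 0.708 (SD 0.053).

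The log2 Dox effect with shRNA-548 minus that with shRNA-942 differed from 0 (limma) for 91 of the 110 genes named, and 6 of these moved in opposite directions. It was 0.66 for TRIM33. Among the genes that rose most it was −0.99 for GSTA1, −0.74 for GSTA2, 1.02 for PGLYRP2, 2.50 for WFDC21P, −0.95 for PLEK2, 1.17 for ERP27, 0.74 for RBP2, 1.11 for MYO1A and 2.01 for CYP7A1. Among those that fell most it was −0.83 for IGFBP1, 1.64 for CCL20, −1.16 for ETV5, 1.88 for ANKRD1, 1.49 for NES, 0.73 for IER3 and −0.20 for SLC2A1. For the genes named for the difference it was 3.80 for CHGB, 3.33 for FSTL3, 3.17 for SOX4, −5.20 for SPP1, −4.70 for BHMT and −3.61 for HEPACAM. For those named in uninduced lines it was 1.00 for HIST1H2AG, 1.17 for HIST1H2BJ, −0.66 for RBM23 and −1.94 for ELK1.

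In the metabolic lists the same difference was 0.14 for LDHA, −0.46 for ENO1, 0.88 for RRM2, 0.99 for GART, 0.26 for PFAS and 0.53 for COQ7. It was −0.41 for HADHB, −1.80 for SLC25A20, −0.51 for HADHA, −0.35 for TM7SF2, −0.41 for LSS, −0.80 for MSMO1 and −0.19 for NSDHL. Among hypoxia targets it was −0.90 for SLC2A3, −0.25 for PDK1 and −0.80 for LOX. Hepatocyte genes had −2.07 for APOA2, −0.93 for SERPINC1, −0.87 for FGG, 1.33 for NR0B2, −0.69 for CYP27A1 and −0.22 for PCK1. Interferon-stimulated genes had −1.87 for IFIT1, 0.72 for IFIH1, 0.50 for MX1 and −0.46 for IFI6.

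In the cell cycle lists the difference was 0.89 for UHRF1, 0.44 for MCM3, 0.86 for CDC45, −0.10 for AURKA, 0.96 for ANLN, 0.17 for BUB1 and −0.29 for CCNB1. Histones had 0.28 for HIST1H2BD, 0.40 for HIST1H2AB, 0.24 for HIST1H4D and 0.18 for HIST1H2BB. Stress and chaperone genes had 0.64 for GDF15, 0.18 for MTHFD2, −0.41 for SLC7A1, −0.35 for STC2, −2.51 for CANX, −1.40 for PDIA4, −0.80 for XBP1, −0.95 for HSPA5, 0.52 for HSPD1, −0.79 for TRAP1 and −0.21 for HSPE1. Ribosomal proteins had −0.83 for MRPS23, −0.89 for MRPL20, 0.41 for MRPL3, −1.97 for RPS27A, 1.83 for RPL26, −0.47 for RPL9 and 0.12 for RPL6. Among genes that Dox changed in both control lines it was −0.69 for GLUD1, 1.58 for SDC4, −0.69 for SLC5A11, 0.22 for DGCR8, −0.49 for SLC6A14, −1.28 for NR6A1, −0.63 for CCDC68, −0.37 for MGC12916 and −0.88 for ENC1.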

How the results depend on the processing

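Scaling by the spike-ins and leaving out replicate 1 of both uninduced control groups were chosen only after the data were seen. Across 19 other settings 150 of 173 counts stayed within 1.5 times the reported value, as did 310 of 312 when a library was left out. Spike-in scaling gave 441 genes for the mean Dox effect of the control lines, 8 in control shRNA-1 and 1608 in control shRNA-2. It gave 6027 for knockdown with shRNA-548, 5180 for the difference between the TRIM33 lines and 1716 for the uninduced lines. The cause was not tested. With spike-in scaling the median gene changed by −0.519 for the mean knockdown, −0.325 with shRNA-548, −0.707 with shRNA-942 and 0.148 in control shRNA-2. With the main scaling these values were 0.044, 0.044, 0.051 and 0.005. In control shRNA-1 library weights gave 2346 genes, its 6 libraries alone 51 and the deposited TPM 386. The causes were not tested. Leaving out a library there gave 310 to 1010 genes. In the other lines the counts from their own 6 libraries stayed within 1.5 times the reported value. A minimum log2 change of 1 was stricter by construction. It left 1, 158, 1584 and 1740 genes for Dox in control shRNA-1, control shRNA-2, shRNA-548 and shRNA-942. For the mean Dox effect of the control lines it left 5. For knockdown it left 1019, 1303, 1461 and 484 (mean, shRNA-548, shRNA-942, both). It left 1089 for the difference, and 1096 and 127 between lines with and without Dox. The small TRIM33 difference in control shRNA-1 turned to −0.036 with library weights, −0.067 with spike-in scaling and −0.035 without the replicates that stood apart; leaving out a library gave −0.035 to 0.062. HADHA (−0.064) and NSDHL (−0.156) turned with spike-in scaling, and ACAA2, HADHB, LSS, MSMO1, CYP27A1 and FGG lost their calls. An estimated correlation left 6 of 17 list calls and fry called 35. Of 255 list results 28 lost their call, and 11 of 408 without a library. A replicate block gave 9569 genes for the mean knockdown and 16 list calls, without the hypoxia targets (adjusted p = 0.0528). No label ties numbers across groups: same-numbered libraries had r from −0.251 to 0.283, with 1 of 12 pairs over 0.1. Depth is unknown and limits low genes.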

Other observations

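The YAP and ERK tests were written before their results were seen, but the lists were drawn up after the named genes were known; the symbol families were also examined only after the data were seen.

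Families of genes sharing a symbol prefix were tested beside the fixed lists. Some share genes with those lists, such as MCM with S phase and MRPL with mitochondrial ribosomal proteins. Their calls are therefore not separate from the list results. There were 154 families of at least 10 genes, tested with camera and the Benjamini-Hochberg method. Of these 9 were called for the mean knockdown, 2 higher and 7 lower, and 0 were called with an estimated correlation. Cytochrome P450 genes (CYP), which metabolize sterols and drugs, had 20 of 22 higher and 1 lower, with a median of 0.91 (adjusted p = 0.000266; adjusted p = 0.148 with an estimated correlation) and of 0.52 with spike-in scaling. Collagen genes (COL) had 13 of 14 higher, with a median of 0.74 (adjusted p = 0.00176; adjusted p = 0.276 with an estimated correlation) and of 0.09 with spike-in scaling. Their medians upon Dox in control shRNA-2 were 0.22 and 0.29.

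On the lower side, nucleoporins (NUP), of the nuclear pore, had 18 of 22 lower and 3 higher, with a median of −0.54 (adjusted p = 0.000407; adjusted p = 0.276 with an estimated correlation). Genes with the prefix MCM, which include subunits of the replicative helicase, had 9 of 11 lower and 0 higher, with a median of −1.25 (adjusted p = 0.000266, or adjusted p = 0.166 with an estimated correlation). Subunits of the RNA exosome (EXOSC) had 9 of 10 lower (adjusted p = 0.0276), UTP ribosome assembly genes 7 of 10 (adjusted p = 0.0477), and DDX helicases 21 of 35 lower and 6 higher (adjusted p = 0.0250). With an estimated correlation the adjusted p was 0.276, 0.372 and 0.318. Ribosomal families MRPL and RPL were also called (adjusted p = 0.0477 each; adjusted p = 0.372 and 0.628 with an estimated correlation). Zinc finger genes (ZNF) had 180 of 416 higher and 104 lower and were not called (adjusted p = 0.492).

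Among the largest falls were ETV4, ETV5 and DUSP6, which are known targets of the ERK pathway. The hypothesis that ERK pathway targets in general were lower was tested on 12 others, none of them a named gene. All 12 fell with the mean knockdown, with a median of −0.922 (95% bootstrap interval −1.264 to −0.617; camera p = 2.32e-05, or p = 0.0172 with an estimated correlation). SPRED1, CCND1 and FOS, chosen after their values were seen, fell by 1.83, 1.02 and 1.56. The median upon Dox was −0.481 in control shRNA-2, where 9 fell and 1 rose, and −0.010 in control shRNA-1. The values are consistent with lower ERK output in induced TRIM33 cells, and in part in induced control shRNA-2 cells, but mRNA levels do not measure ERK activity.

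A like hypothesis for YAP targets, from ANKRD1, was left open. Of 16 others 8 fell and 5 rose, with a median of −0.374 (95% bootstrap interval −0.752 to 0.237). The interval spans 0, and the group did not pass limma's camera.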
